A study of Mus musculus with 13 samples.

How the data were processed

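RNA sequencing was done on 13 mouse libraries in 2 parts. The tissue part held 7 libraries from the hippocampus of 3xTg mice, a model of Alzheimer disease that carries mutant human amyloid precursor protein and tau transgenes under Thy1 control. In 3 of them the mice had received control adeno-associated virus 9 (AAV9), and in 4 of them AAV9 carrying Nurr1 (gene symbol Nr4a2) and Foxa2, written N+F here. The labels also give amyloid beta as the treatment of all 7 tissue libraries. The culture part held 6 libraries of glia from postnatal day 1 pups of the ICR strain, 1 library per group. Hippocampal and cortical glia each had a control lentivirus without amyloid beta (called untreated), a control lentivirus with amyloid beta (called amyloid beta control) and an N+F lentivirus with amyloid beta. Groups and replicate numbers were taken from the sample titles.

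The deposited values were counts per gene symbol, whole numbers whose totals differed between libraries. RNA was extracted with Trizol and 1.3 µg of total RNA went into SMARTER mRNA-seq libraries, per the labels' protocols. TopHat, HISAT2 and edgeR were used, per the submitters' processing notes, which give no version or role for any of them. The notes also name the human build hg19, although the tables hold mouse symbols. Because of that the build behind the counts was treated as not established, and no coordinates are given. The mouse annotation GRCm38.p6 was used for gene names and for which genes are neighbours. Whether reads were counted by strand, and whether transcripts of the viral vectors were among the counted features, is not given in the sources used here. The tissue table had 23282 lines, of which 44 repeated a symbol. The culture table had 36780 lines, of which 12238 repeated a symbol with other values. Lines of a symbol were summed, which left 23238 and 24542 symbols. If the authors counted a read in several lines of a symbol, the sum counts it more than once, so levels of genes with many lines may be overstated. No sum crosses libraries, so ratios within a gene are less affected. Of these symbols 23152 and 24451 matched a current or older mouse gene symbol. Each column matched 1 sample title, and 0 columns were left unused. No line lacked a gene name.

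Tissue totals ran from 10194437 to 25139406 counts per library, with 17739 to 20221 symbols counted. Culture totals ran from 52189025 to 78273121 counts, with 16850 to 18164 symbols counted. At these depths the floor of 3 counts that a count of 0 allows lies far below 1 CPM (counts scaled to a common library total). Folds against a count of 0 were set against that floor of 3 counts per library and are written as lower bounds, and a ratio that rests on 1 to 3 counts has its 95% counting interval. Such intervals and floors cover counting error only. All pairs of replicate tissue libraries differed by more than sampling noise (chi-square per gene 15.0 to 56.1 over symbols of at least 50 counts in the pair), so none was treated as a repeat deposit. Nothing in the labels says that the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

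Tissue libraries were compared with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test on counts after filtering with filterByExpr by group and TMM scaling (factors 0.895 to 1.11). p-values were adjusted by the Benjamini-Hochberg method over 15523 genes, with 0.05 as the threshold. The biological coefficient of variation was 0.206. Printed tissue levels are TMM-scaled CPM as mean ± SD, except for Foxa2. Foxa2 did not pass the count filter in tissue, is given as CPM of the library total and was compared by a two-sided exact permutation test. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over 20 pathway lists and over 16 marker lists. The pathway lists covered microglial, inflammatory, astrocytic, amyloid, lysosomal, metabolic, trophic, synaptic, stress and growth genes. The marker lists covered the cell types of brain tissue and of neighbouring regions that a dissection could carry. Culture libraries had no replicates. Their values are CPM of the library total, and each difference is a log2 ratio of CPM + 1. A gene was counted as changed when it differed at least 2-fold the same way in hippocampal and cortical glia and reached 1 CPM in a library of each pair. For a list, the median log2 ratio was placed among 10000 random lists of the same size matched on mean level in 20 bins, and called extreme at a percentile above 97.5 or below 2.5. A secondary edgeR fit on 16762 genes used region and condition as additive terms. It had 2 residual degrees of freedom, and its spread is how far the regions differ in response.

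Named genes were chosen by rule. In tissue these were the genes past the test whose N+F libraries all lay on one side of all controls, with a mean of at least 1 CPM, at most 8 per direction, ranked by fold change. In cultures they were the 8 highest and 8 lowest genes per contrast by the smaller of the 2 log2 ratios. Nr4a2, Foxa2, App, Mapt and Thy1 were always named, as were up to 4 members per described list, in tissue those of smallest p and in cultures those of largest mean ratio. The other genes past the tissue test were named after their values were seen, as were some further list members. Some results that the rule covers are not reported here. Groups, tests, lists, the naming rule and the other settings first listed were fixed before the data were examined.

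The scripts were tested on simulated data. In the simulated tissue comparison of 15314 genes, 64.0% of 2-fold and 94.9% of 4-fold changes were recovered, with 7 false calls. In the simulated additive fit of N+F over 16536 genes, 1.43% of 2-fold, 18.6% of 4-fold and 90.0% of 32-fold changes were recovered, with 3 false calls. The rule of a 2-fold difference in both cultures recovered 77.6% of simulated 4-fold changes, and of the 14358 simulated genes it covered it passed 206 that had been left unchanged. A simulated list raised 1.5-fold was at percentile 90.85 in hippocampal and 100 in cortical glia, and an unchanged list at 46.55 and 17.15. Alternatives included DESeq2 1.42.0, other size factors, other filters, pseudocounts and fold limits, fry and an estimated correlation for the lists, the replicate number as a block, and each library left out in turn. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The tissue and culture tables were never merged for a test, and were compared only by sign, by marker level and by rank across genes.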

Results

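Gene expression was measured as counts in 7 hippocampus libraries of 3xTg mice and in 6 libraries of cultured glia. The tissue set had 3 libraries with control AAV9 and 4 with N+F AAV9. Control libraries 1, 2 and 3 held 25139406, 12092488 and 12571452 counts, and N+F libraries 1 to 4 held 10194437, 11123613, 11319951 and 12260884. The ribosomal RNA precursor Rn45s took 2.45 to 5.70% of tissue counts. The untreated, amyloid beta control and amyloid beta with N+F libraries held 67579963, 74717389 and 60465788 counts in hippocampal glia and 52189025, 60721684 and 78273121 in cortical glia. Each culture group was a single library, so culture values have no replicate error.

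The tissue comparison asked which transcripts differed in 3xTg hippocampus after AAV9 carried Nurr1 and Foxa2. The genes that fell included Fibcd1, Spink8 and Neurod6 of hippocampal pyramidal neurons and the collagen genes Col1a1, Col5a1 and Col12a1. Fibcd1, a receptor enriched in CA1, fell by 1.89 ± 0.23 on the log2 scale (SE), from 24.8 ± 6.20 to 6.69 ± 1.68 CPM (SD, n = 3 and 4; edgeR adjusted p = 0.0267). Spp1, the secreted matrix protein osteopontin, fell by 1.97 ± 0.25, from 65.6 ± 26.5 to 16.7 ± 3.15 CPM (edgeR adjusted p = 0.0267). Nts, the precursor of the neuropeptide neurotensin, rose by 1.21 ± 0.20, from 13.8 ± 1.42 to 32.0 ± 7.80 CPM (edgeR adjusted p = 0.0481).

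Of 15523 genes tested, 1 rose and 16 fell, and in all 17 the N+F libraries lay on one side of all controls. Among the collagens, Col5a1 fell by 2.02 ± 0.28 (23.9 ± 8.46 to 5.83 ± 1.61 CPM) and Col12a1 by 1.97 ± 0.26 (13.4 ± 4.11 to 3.37 ± 0.617 CPM), each with an adjusted p of 0.0267. The fibrillar collagen gene Col1a1 fell by 4.21 ± 0.65 (adjusted p = 0.0375), but its control libraries were uneven, with 12.03 CPM in control 1 against 140 and 138 in the others. Neurod6, a transcription factor of pyramidal neurons, fell by 1.33 ± 0.19 (37.8 ± 6.62 to 15.01 ± 3.44 CPM, adjusted p = 0.0342). Il16, the neuropeptide gene Grp and the CA1 marker Spink8 fell by 1.82 ± 0.24, 1.69 ± 0.23 and 1.51 ± 0.24, with adjusted p of 0.0267, 0.0267 and 0.0436. Cemip, an enzyme of hyaluronan breakdown, fell by 2.10 ± 0.33 (adjusted p = 0.0375). Gabra5, a GABA receptor subunit, fell by 1.02 ± 0.15, from 38.6 ± 2.47 to 18.9 ± 3.17 CPM (adjusted p = 0.0371). Cabp7, Fezf2, Iqgap2, Golm1 and Plekhg5 fell by 1.41, 1.27, 1.18, 1.00 and 0.86, with adjusted p from 0.0370 to 0.0375. At an unadjusted p under 0.05 there were 1313 genes. Groups did not overlap in 1259 genes, 8.11% against the 5.71% that chance gives.

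The calls depended on single libraries. Without control 1 there were 29 calls, 13 of them among the 17. Without control 2 there were 3 calls and without control 3 there was 1, of which 1 and 0 were among the 17. With any 1 N+F library left out edgeR called 0 genes, with 1066 to 1544 at an unadjusted p under 0.05, and the 17 genes then had adjusted p from 0.0571 to 0.207. With all 7 libraries DESeq2 called 131 genes, which included all 17.

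**Figure D1:**
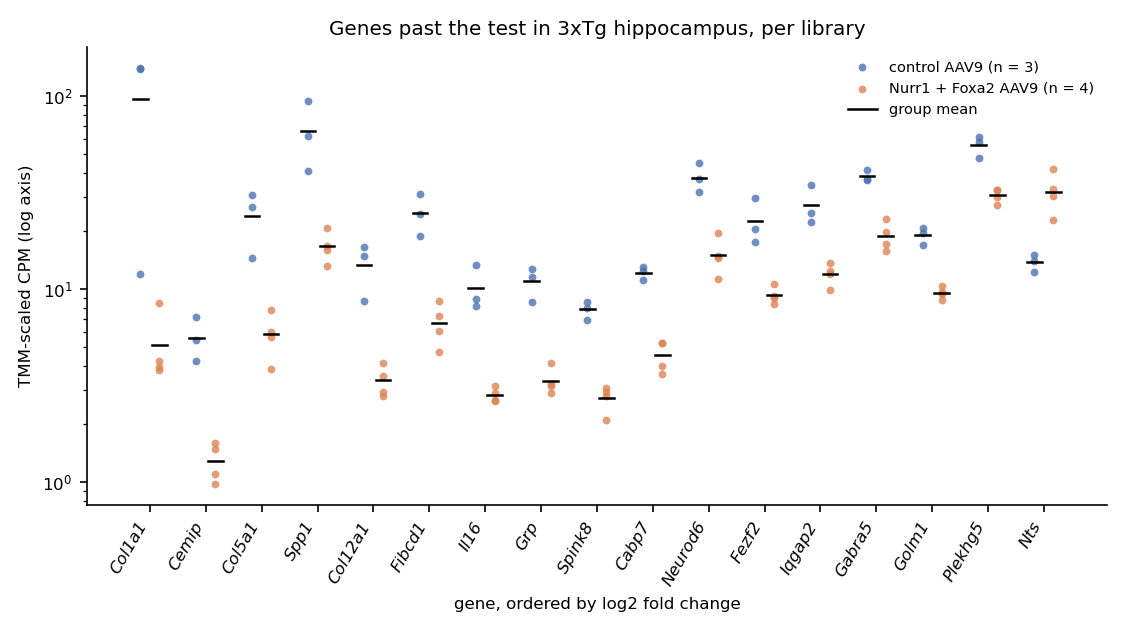
TMM-scaled CPM on a log axis of the 17 genes past the test, 1 point per library, with bars at the group means of 3 control and 4 N+F libraries. Nts is the 1 gene that was higher with N+F, and Col1a1 has 1 control at 12.03 CPM apart from the other controls.

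The genes carried by the vector were not among the calls. Nr4a2 measured 31.5 ± 12.7 CPM in controls and 27.0 ± 4.85 with N+F (log2 fold change -0.22 ± 0.24, adjusted p = 0.872), and without control 3 the fold change was 0.11. Foxa2 was below the count filter, with raw counts of 5, 1 and 1 in controls and 26, 5, 1 and 6 with N+F. Its level as CPM of the library total, without TMM scaling, was 0.120 ± 0.0680 against 0.894 ± 1.12 CPM (two-sided exact permutation p = 0.114). With so few libraries the smallest possible one-sided permutation p is 0.0286, and the two-sided p cannot go as low. The smallest possible two-sided p lies above the threshold used for edgeR, so this test cannot decide whether Foxa2 differed. Of the Foxa2 counts with N+F, 68.4% were in N+F library 1. Of genes linked to the mouse model, App had a log2 fold change of -0.26 ± 0.17 (adjusted p = 0.749), Thy1 -0.40 ± 0.18 (0.569) and Mapt 0.02 ± 0.15 (0.990). The sources used here do not say whether human transgene or vector transcripts would be counted under these symbols.

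Genes of glial reaction fell as lists in the N+F hippocampus at the preset correlation, but not with an estimated correlation or with fry. Of 34 reactive astrocyte genes 33 had negative fold changes, with a median of -0.54 (camera adjusted p = 5.84e-08; adjusted p = 0.337 with an estimated correlation). Adjusted over the list alone, 1 gene fell, the complement factor C3, from 21.6 to 8.33 CPM. Emp1, Timp1 and Cd44 had log2 fold changes of -1.58, -1.19 and -0.91. Timp1 was uneven in controls, with 7.45 CPM in control 1 against 22.7 and 17.9 in the others, and 3.94 to 8.79 with N+F. Of 26 disease-associated microglia genes 24 were negative, with a median of -0.44 (adjusted p = 8.59e-08; adjusted p = 0.399 with an estimated correlation). Spp1 was called over all genes, and 8 fell adjusted over the list alone; Gpnmb, Lyz2 and Csf1 had -1.66, -1.47 and -0.60. Of 18 complement genes 16 were negative, with a median of -0.46 (adjusted p = 0.000123; adjusted p = 0.337 with an estimated correlation), among them C1ra (-1.10), C1qa (-0.57) and C1qc (-0.49). C3 is in this list too. Microglia, endothelial, and mural and fibroblast markers also fell at the preset correlation, while astrocyte markers did not pass (median -0.14, camera adjusted p = 0.144). Less RNA of such cells was not told apart from a change within them.

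Lists of respiration and of neuronal activity genes had positive medians, though 0 oxidative phosphorylation genes passed the test, also when adjusted over the list alone. Of 30 oxidative phosphorylation genes 29 had positive fold changes, with a median of 0.15 (adjusted p = 0.000189; adjusted p = 0.457 with an estimated correlation), among them Ndufa1 (0.34), Cox7c (0.28), Sdhb (0.27) and Cox5a (0.23). Of 20 immediate early genes 14 were positive, with a median of 0.38 (adjusted p = 0.00407; adjusted p = 0.399 with an estimated correlation). Adjusted over the list alone Fos (0.80), Nr4a1 (1.01) and Egr4 (0.91) rose and Jun (-0.65) fell. Lysosome and autophagy genes had a median of -0.12 with 21 of 30 negative (adjusted p = 0.0182; adjusted p = 0.399 with an estimated correlation), and Ctsd, Grn and Lipa had -0.49, -0.42 and -0.51. Without control 1 the adjusted p was 0.112 for oxidative phosphorylation and 0.115 for immediate early genes, and without control 2 it was 0.180 for lysosome genes. The number of pathway lists past the test ran from 4 without control 1 to 10 without N+F library 3. None of the 6 held with an estimated correlation or with fry.

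**Figure D2:**
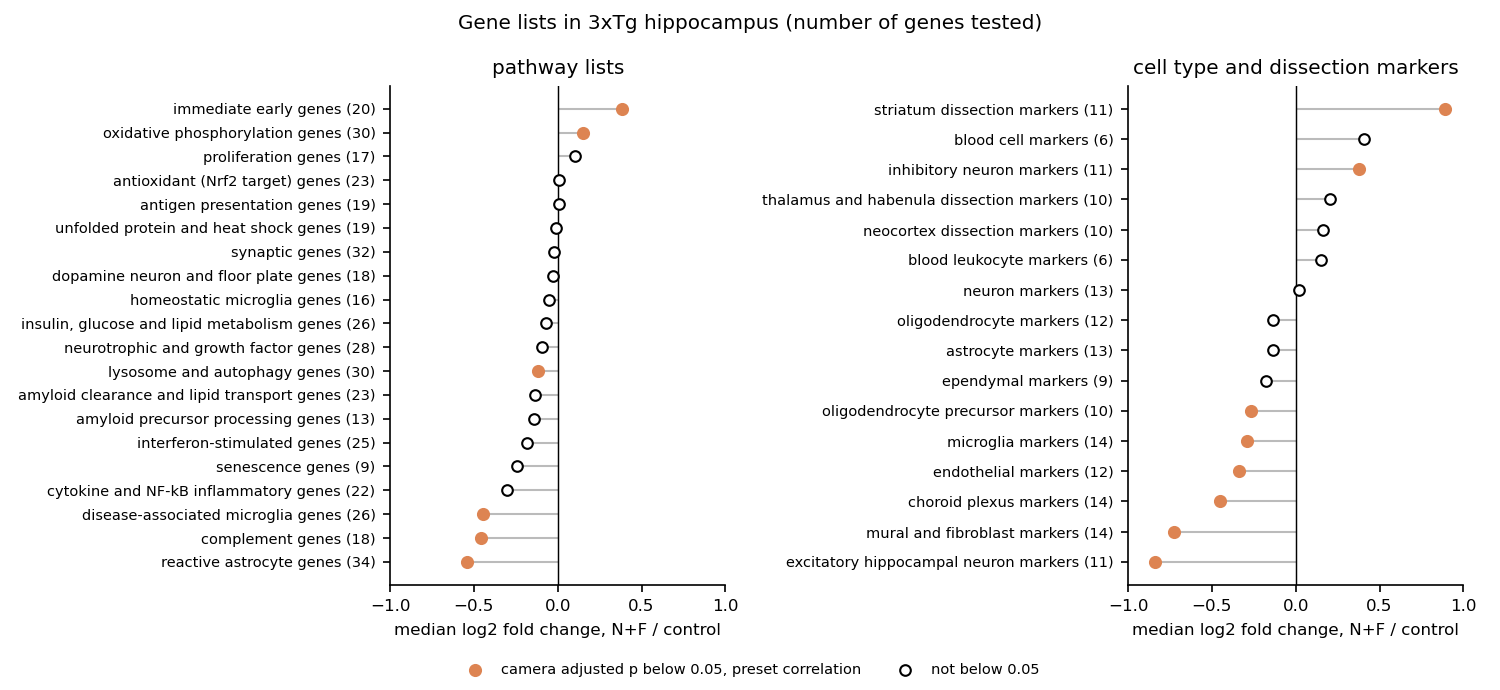
Median log2 fold change of N+F to control hippocampus for 20 pathway lists and 16 marker lists, with the number of genes tested in brackets. Filled points mark a camera adjusted p below 0.05 at the preset correlation, which 6 pathway and 8 marker lists reached.

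Cell type and region markers differed between the same tissue groups. Excitatory hippocampal neuron markers fell, with a median of -0.84 over 11 genes (adjusted p = 2.21e-06; adjusted p = 0.246 with an estimated correlation), and their median level per library was 37.0, 41.2 and 44.8 CPM in controls against 11.2, 14.8, 14.4 and 19.6 with N+F. Fibcd1, Neurod6 and Spink8 were called over all genes, and 6 fell adjusted over the list alone, among them Neurod2 (-0.84). Striatum dissection markers rose, with a median of 0.89 and 11 of 11 positive (adjusted p = 2.21e-06; adjusted p = 0.391 with an estimated correlation), including Tac1 (1.00), Penk (0.83), Gng7 (0.67) and Rarb (0.41). Their level varied within groups, at 80.1, 15.5 and 129 CPM in controls and 199, 165, 123 and 72.8 with N+F. Mural and fibroblast markers fell, with a median of -0.72 (adjusted p = 4.51e-06; adjusted p = 0.246 with an estimated correlation). Their median level was 10.1 CPM in control 1 against 21.7 and 20.5 in the other controls, and 5.07, 9.21, 7.16 and 7.80 with N+F. Col1a1 was called, and 4 fell adjusted over the list alone, Col1a1, Col1a2 (-4.09), Col3a1 (-2.44) and Fn1 (-1.21). In control 1 Col1a2 was 8.09 CPM against 125 and 113 in the other controls, and Col3a1 2.83 against 14.04 and 7.59. Endothelial markers fell with a median of -0.34 and 12 of 12 negative (adjusted p = 1.46e-05; adjusted p = 0.246 with an estimated correlation), and Flt1 (-0.78), Cdh5 (-1.09) and Kdr (-1.36) fell adjusted over the list alone. Inhibitory neuron markers rose with a median of 0.38 (adjusted p = 0.00504; adjusted p = 0.246 with an estimated correlation), and 6 rose adjusted over the list alone, among them Gad2 (0.43), Lhx6 (0.53) and Slc32a1 (0.55). Choroid plexus (-0.45, adjusted p = 0.00199), microglia (-0.29, 0.00274) and oligodendrocyte precursor markers (-0.27, 0.0207) passed the test with negative medians. With an estimated correlation these 3 lists had adjusted p = 0.575, 0.403 and 0.405, and with fry none of the 8 marker lists held. The median choroid plexus level was 5.14, 4.01 and 3.28 CPM in controls and 1.61, 2.01, 1.78 and 6.998 with N+F, so that N+F library 4 lay above all controls. The choroid plexus transcript Ttr was 3901 CPM in that library against 1115 to 2830 in controls. Choroid plexus markers had an adjusted p of 0.0574 without control 1, and precursor markers 0.287 without control 1 and 0.103 without N+F library 2.

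The other lists did not pass in tissue. Medians and adjusted p were -0.14 and 0.0730 for amyloid precursor processing, -0.30 and 0.0782 for cytokine and inflammatory genes, -0.18 and 0.0810 for interferon-stimulated genes, -0.02 and 0.111 for synaptic genes and -0.05 and 0.167 for homeostatic microglia genes. Mmp9 (-2.53) fell adjusted over the cytokine list alone, and Tgfb2 (-0.88) and Thbs2 (-1.28) adjusted over the neurotrophic list alone, which had -0.10 and 0.208. Amyloid clearance had -0.13 and 0.172, senescence -0.24 and 0.280, and insulin, glucose and lipid metabolism -0.07 and 0.651. Antigen presentation (0.00, 0.646), antioxidant (0.01, 0.724), unfolded protein (-0.01, 0.786), proliferation (0.10, 0.886) and neuron markers (0.02, 0.909) had medians, means and tests that differed in sign. Dopamine neuron genes had -0.03 and 0.981. Among markers, oligodendrocyte had -0.13 and 0.0696, neocortex 0.17 and 0.135, astrocyte -0.14 and 0.144, ependymal -0.18 and 0.176, blood cell 0.41 and 0.211, thalamus 0.20 and 0.385 and leukocyte 0.15 and 0.909. In the neocortex list Fezf2 was called lower, while Lamp5 (0.54) and Rspo1 (0.68) rose adjusted over the list alone.

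In the cultures the amyloid beta comparison set the amyloid beta control library against the untreated library of each region. Innate immune and reactive astrocyte transcripts were higher and neuronal transcripts lower with amyloid beta in both regions. Lcn2, a secreted iron-carrier binding protein of reactive astrocytes, went from 0.873 to 7535 CPM in hippocampal and from 0.115 to 7136 CPM in cortical glia. C3 went from 1.45 to 6072 and from 0.287 to 5888 CPM. Snap25, a synaptic vesicle fusion protein, went from 2093 to 0.509 and from 2709 to 1.42 CPM. The untreated libraries also differed in cell type markers. Neuron markers had a median of 336 and 286 CPM there against 2.82 and 1.83 CPM in the amyloid beta control. Oligodendrocyte markers had 279 and 226 against 3.99 and 0.412 CPM. All amyloid beta ratios of the cultures therefore hold any difference in cell content too.

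Of 14516 genes, 2408 were at least 2-fold higher and 3123 at least 2-fold lower in both regions, where 607 and 929 would overlap by chance. That chance value takes the regions as independent, while the untreated libraries of both differed alike in cell type markers (r = 0.94 between the regions' ratios). The excess therefore says little of amyloid beta itself. The edgeR additive fit called 2661 genes higher and 2882 lower. Without the hippocampal untreated, hippocampal amyloid beta control, cortical untreated or cortical amyloid beta control library it called 1072, 794, 988 and 1308 higher and 1535, 1156, 1511 and 1523 lower. The named genes of largest ratio (log2, hippocampal and cortical) were Lcn2 (11.97, 12.64), C3 (11.28, 12.16), Steap4 (8.36, 9.06), Serpina3h (8.88 in hippocampal glia), Chil1 (8.40, 8.09), Ptx3 (8.76, 7.52), Vim (7.44, 7.79) and Thbs1 (7.32, 8.50). Serpina3h had 0 counts in untreated cortical glia and was at least 5405-fold higher there. It belongs to a cluster of similar genes, so its reads may be shared. The lowest were Snap25 (-10.44, -10.13), Nrgn (-9.92, -10.41), Slc17a7 (-8.94, -9.50), Vsnl1 (-9.49 in cortical glia), Snhg11 (-8.90, -9.64), Meg3 (-8.88, -9.17), Sv2b (-8.80 in hippocampal glia) and Ttr (-11.90, -8.78). With amyloid beta Vsnl1 had 0 counts in hippocampal glia, at least 12174-fold lower, and Sv2b 0 counts in cortical glia, at least 9486-fold lower. Nr4a2 was lower (-3.77, -1.70), as were Mapt (-5.14, -4.36) and App (-0.73, -0.61), while Thy1 had 0.10 and 1.16. Foxa2 had 0 counts in the untreated and amyloid beta control libraries of both regions, so no fold is given.

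Medians of 13 of 20 pathway lists were extreme among random lists in both regions with amyloid beta. Interferon-stimulated genes had medians of 3.70 and 4.28, with 24 and 26 of 26 at least 2-fold higher, among them Ifi44 (4.91, 6.50), Isg15 (5.17, 5.93) and Ifitm3 (5.56, 5.56). Reactive astrocyte genes had 3.82 and 4.02, with 33 and 31 of 38 higher. Cytokine genes had 2.39 and 3.02, among them Cxcl10 (6.75, 6.07). Ccl2 had 0 counts in both untreated libraries and was at least 1936- and 1707-fold higher. Cxcl1 rested on 2 untreated counts in hippocampal glia, with a ratio of 6145 (95% counting interval 1701 to 50743), and on 0 in cortical glia, where it was at least 2564-fold higher. Disease-associated microglia genes had 2.09 and 2.38, with Spp1 (5.31, 5.27) and Csf1 (4.50, 4.73), while homeostatic microglia genes had -3.26 and -3.44, with P2ry12 (-4.52, -4.53) and Cx3cr1 (-4.12, -4.49). Antioxidant genes had 2.32 and 1.66, with Hmox1 (7.02, 5.76), and senescence genes 3.67 and 2.73, with Igfbp3 (6.77, 8.26) and Cdkn2b (7.15, 5.78). Antigen presentation had 1.72 and 2.59, neurotrophic 1.28 and 0.90, proliferation 1.26 and 0.87, complement 0.84 and 0.82 and amyloid clearance 0.84 and 0.84. Synaptic genes had -4.82 and -4.72, with 30 of 32 lower in each region. The other lists had 0.35 and 0.50 (amyloid precursor processing), 0.61 and 0.51 (lysosome), 0.53 and 0.56 (oxidative phosphorylation), -0.26 and -1.05 (immediate early), -2.25 and -1.50 (dopamine neuron), 0.16 and 0.75 (unfolded protein) and 0.53 and 0.46 (insulin and glucose). Beside these lists, microglia markers went from 41.8 to 4.38 and from 42.1 to 9.61 CPM, endothelial markers from 25.6 to 0.723 and from 29.9 to 0.758 CPM, and astrocyte markers from 216 to 490 and from 198 to 501 CPM.

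**Figure D3:**
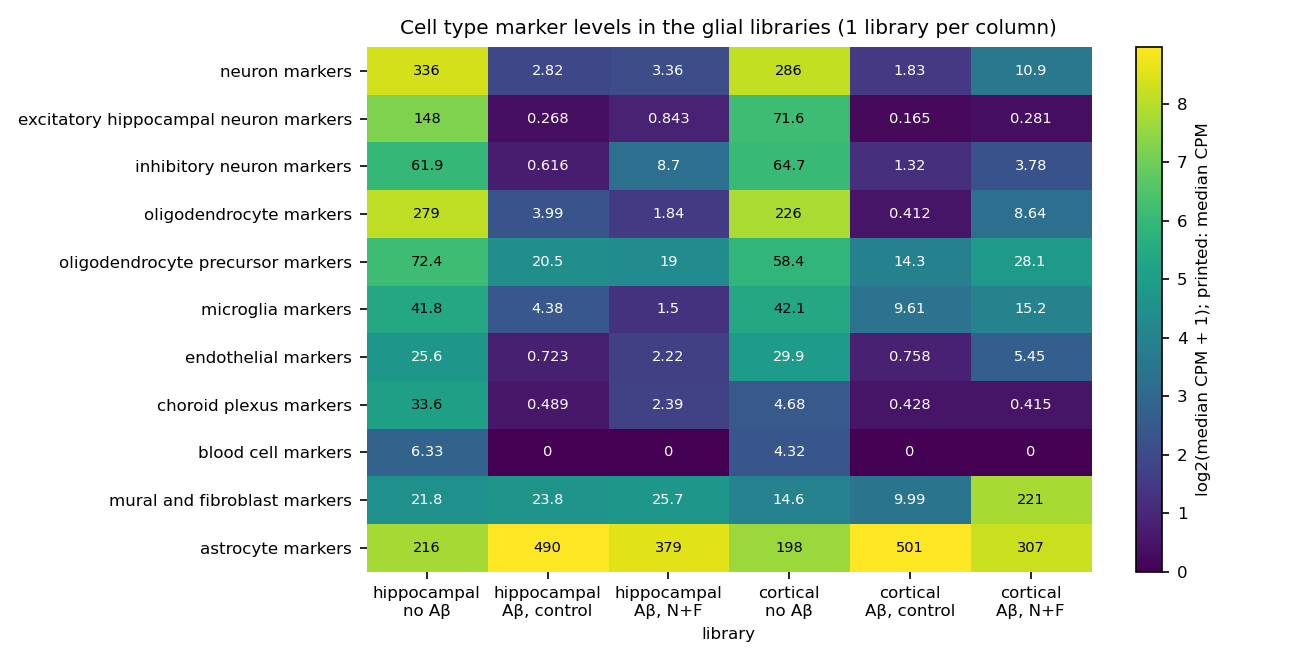
Median CPM of 11 marker lists in the 6 glial libraries, 1 library per column, coloured by log2 of the median CPM + 1. Neuron markers stand at 336 and 286 CPM without amyloid beta and at 1.83 to 10.9 CPM in the other libraries.

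The N+F comparison in culture set N+F against control lentivirus, both with amyloid beta. Both delivered genes were higher in both regions. Foxa2 had 0 counts in the controls and 140 CPM with N+F in hippocampal glia (at least 3494-fold higher against a floor of 3 counts per library) and 13.5 CPM in cortical glia (at least 274-fold higher). Nr4a2 went from 3.35 to 488 CPM (146-fold) and from 5.14 to 36.9 CPM (7.19-fold). Lepr, the leptin receptor, was higher in both (log2 ratios 6.22 and 7.23). Tnf, the inflammatory cytokine, was lower, from 1.93 to 0.397 and from 3.11 to 0.409 CPM. However, it was among only 16 genes lower in both regions, where 16.2 would overlap by chance. The cytokine list that holds Tnf did not fall in both regions, with median log2 ratios of -0.14 and 0.36.

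Of 13479 genes, 279 were at least 2-fold higher and 16 at least 2-fold lower in both regions, where 77.4 and 16.2 would overlap by chance. That chance value treats the regions as independent for every gene. In simulated data the same rule passed 206 unchanged genes of 14358, both directions together. In hippocampal glia 667 were higher and 105 lower, and in cortical glia 1564 and 2076. The ratios of the regions had r = 0.18 across genes, which are not independent replicates. The edgeR additive fit called 0 genes in either direction, with 1156 at an unadjusted p under 0.05, where DESeq2 called 420 higher and 57 lower. The median of all genes was 0.12 in hippocampal and -0.18 in cortical glia, so smaller ratios depend on the scaling. Other named higher genes were Medag (4.39, 3.96), Fbn2 (3.85, 4.57), Postn (3.26, 4.17), Tmem254c (3.16, 2.87) and Nps (6.22 in hippocampal glia). Kng1 went from 0 counts to 54.1 and 10.6 CPM, at least 1348- and 215-fold higher. Cortical Nps was at 0 in the control, at least 127-fold higher, and cortical Lepr rested on 3 control counts, with a ratio of 3179 (95% counting interval 1087 to 15415). The lower genes were Tmem254a (-2.16, -2.64), Acod1 (-1.20, -2.71), Slc38a3 (-1.13, -1.55), Aldoc (-1.07, -2.79), Tnf (-1.07, -1.55), Fpr1 (-1.06, -1.14), Rapgef3 (-1.06, -1.28) and Slc39a12 (-1.05, -1.53). Tmem254a and Tmem254c are near-identical copies, so how reads were shared between them decides their values. App had -0.10 and 0.33, Mapt -0.17 and -0.98 and Thy1 -0.40 and -1.38.

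**Figure D4:**
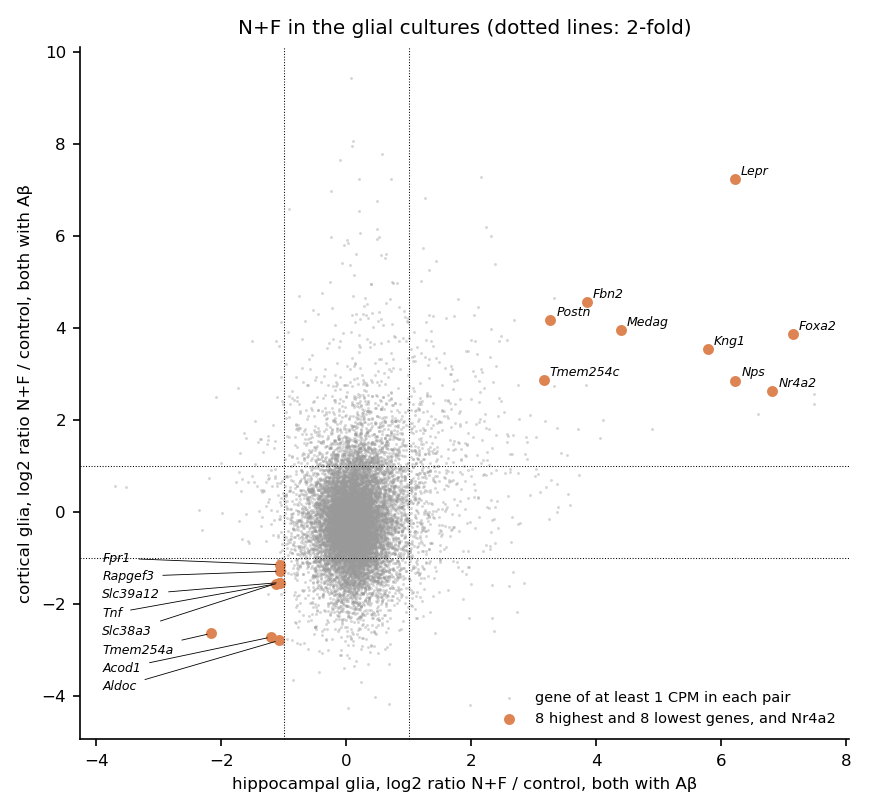
Log2 ratio of N+F to control, both with amyloid beta, in hippocampal against cortical glia, 1 point per gene, with dotted lines at 2-fold. The labelled genes lie beyond the lines in both regions, as do 279 genes in all on the higher side and 16 on the lower.

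With N+F, 6 of 20 pathway lists were extreme the same way in both regions. Immediate early genes had medians of 0.52 and 1.24, with Egr1 (1.70, 2.67), Dusp1 (1.29, 1.92) and Klf4 (0.98, 2.47). Proliferation genes had 0.71 and 0.85, with Mki67 (1.45, 1.33) and Cenpe (1.17, 0.85). Dopamine neuron and floor plate genes, had 3.55 and 0.92, with Ret at 3.72 and 0.80. Only 6 of 22 were measured, among them the delivered Foxa2 and Nr4a2, and Foxa2 was measured only through its N+F libraries, so the place of this list among the 6 says little of its other genes. Unfolded protein genes had 0.31 and 0.30. Interferon-stimulated genes had -0.03 and -0.75, with Isg15 at -0.53 and -1.54 and Oas1a at -0.36 and -1.55, and oxidative phosphorylation genes -0.09 and -0.52. In hippocampal glia 25 of 26 interferon-stimulated and 30 of 30 oxidative phosphorylation genes lay within 2-fold. Their medians ranked low there against a median of 0.12 over all genes. Several inflammatory and glial lists went opposite ways in the regions, a difference that was not tested. Antigen presentation genes and astrocyte markers did not. Disease-associated microglia genes had -0.47 in hippocampal and 1.10 in cortical glia, with Lyz2 (-1.61, 1.62) and Tyrobp (-1.41, 1.53), complement genes -0.66 and 0.79, cytokine genes -0.14 and 0.36 and reactive astrocyte genes -0.12 and 0.25. Microglia markers, among which Tyrobp also is, had -0.88 and 0.79, from 4.38 to 1.505 CPM in hippocampal and from 9.61 to 15.2 CPM in cortical glia. Mural and fibroblast markers had 0.10 and 2.06, from 9.99 to 221 CPM in cortical glia, with Col3a1 (0.08, 9.42) and Dcn (0.57, 7.79), and oligodendrocyte markers -0.75 and 2.53, with Mbp (-0.92, 6.59). The N+F ratios of single genes in cortical glia, such as Lepr, may therefore hold a difference in cell content too, which was not tested. Astrocyte markers had -0.45 and -0.50, neuron markers 0.61 and 0.86, endothelial 0.45 and 1.49, choroid plexus 0.34 and 0.64, inhibitory neuron 0.50 and 0.35 and ependymal -0.48 and 0.06. The remaining lists had -0.02 and 0.15 (homeostatic microglia), 0.17 and 0.26 (antigen presentation), 0.04 and 0.25 (amyloid precursor processing), -0.01 and 0.68 (amyloid clearance), -0.06 and 0.57 (lysosome), -0.41 and 0.16 (antioxidant), 0.04 and 0.75 (neurotrophic), 0.19 and -0.29 (synaptic), -0.05 and 1.70 (senescence) and 0.06 and -0.04 (insulin and glucose).

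Whether N+F moved genes back against amyloid beta was asked across regions, so that no library was shared. Across 11928 genes the amyloid beta ratio of hippocampal glia and the N+F ratio of cortical glia had r = 0.02 (rho = 0.07), and the reverse pair had r = -0.20 (rho = -0.22). Of 3055 genes higher with amyloid beta in hippocampal glia, 50.2% were lower with N+F in cortical glia, against 59.8% of all genes. Of 2885 genes higher in cortical glia, 52.7% were lower with N+F in hippocampal glia, against 36.3% of all genes. These shares cover genes that also reached 1 CPM in the N+F pairs, which a gene lower with amyloid beta may do only because N+F raised it. Genes lower with amyloid beta were therefore counted without that minimum, a setting chosen after the data were seen. Of 3697 such genes in hippocampal glia, 46.9% were higher with N+F in cortical glia, against 41.1% of 14516 genes, and of 3649 in cortical glia, 65.1% were higher with N+F in hippocampal glia, against 63.0%. The amyloid beta ratios here are against the untreated libraries, in which neuron markers had medians of 336 and 286 CPM, so they hold any difference in cell content too. Within a region the correlations were -0.25 and -0.14, and there the ratios share a library. Simulations without any effect gave -0.50, but they held no amyloid beta differences, unlike these data (2408 genes higher and 3123 lower in both regions). Such differences weaken the correlation that a shared library builds in, so -0.50 is no baseline here and nothing was concluded.

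The genes called in tissue were then looked up in the cultures. Of the 17, 9 were measured there and 1, Plekhg5, had the tissue sign with N+F in both regions. That is 11.1% (exact binomial 95% interval 0.281 to 48.2%), against 23.8% of 12763 genes, at percentile 30.9 of matched random sets.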

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

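Chosen after their results were seen were the test of amyloid beta alone and the 4 tests of the runs of neighbouring genes. The CA1 median with the called genes kept was also added later. The others in this part were planned before their own results were seen. However, the CA1, CA3 and dentate lists were chosen after the tissue results were seen.

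Among 73 values tested in the 4 N+F tissue libraries, 4 had 1 library far from the others, where 3.65 would by chance. Col1a1 was 8.48 CPM in N+F library 4 against 3.82 to 4.25 in the others. Kcnj13, a choroid plexus channel, was 8.16 CPM in the same library against 1.61 to 2.68. Sdhb, a respiratory chain subunit, was 256 CPM there against 293 to 298. Foxa2 was 2.55 CPM in N+F library 1 against 0.0883 to 0.489.

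In the cultures several N+F effects had opposite signs in the regions, with a single library each, and the differences were not tested. Hippocampal and cortical medians were -0.47 and 1.10 for disease-associated microglia genes, -0.14 and 0.36 for cytokine genes, -0.66 and 0.79 for complement genes and -0.12 and 0.25 for reactive astrocyte genes. They were -0.75 and 2.53 for oligodendrocyte markers, -0.16 and 2.12 for oligodendrocyte precursor markers and -0.88 and 0.79 for microglia markers. App had -0.10 and 0.33.

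The untreated glial libraries carried neuron and oligodendrocyte transcripts at far higher median levels than the other cultures. They may hold whole-tissue RNA: their rank correlation across genes was higher with the hippocampus tissue controls than with the amyloid beta control culture of their own region, by 0.0526 in cortical and 0.0632 in hippocampal glia. Had amyloid beta alone changed otherwise equal glial cultures, the untreated libraries were predicted to hold neuron, endothelial and blood cell markers at low levels. Neuron markers stood at 336 and 286 CPM there, against 284 to 310 TMM-scaled CPM in the hippocampus tissue controls. Endothelial markers stood at 25.6 and 29.9 CPM, while blood cell markers were low, at 6.33 and 4.32 CPM. The neuron and endothelial values argue against otherwise equal cultures. What amyloid beta itself changed cannot be told apart, since treatment and cell content changed together. The amyloid beta differences of the cultures therefore rest on libraries that also differ in cell type marker levels.

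For the CA1 and collagen genes that were lower in the N+F hippocampus, chance was not excluded. Of 35 splits of the 7 libraries the real one gave the most genes (17, with 10 the highest of the others). That count covers all 17 genes, and 1 of 35 is the smallest share such a test can give. Without the deeper control 1, 16 of the 16 lower genes kept a 1.5-fold difference. This was nearly fixed by their choice, as in each of them all controls lay above all N+F libraries. The edgeR test still called 13 of the 16 without control 1, so those 13 do not rest on that library alone. Less fibroblast and mural RNA stays open and is consistent with their markers outside the called genes, with a median of -0.63 (p = 9.27e-06, but 0.0656 with an estimated correlation). Less CA1 tissue cannot be told apart from an effect of N+F within cells, which was untested: CA1 markers outside the called genes had a median of -0.18, above the bound of -0.3 set in advance, their limma camera p was 0.407, and CA3 (-0.22) and dentate markers (-0.52) lay below them and not above. These values cannot decide it, since the list leaves out the called CA1 markers, which had a median of -1.51. Setting the bounds on such a list was wrong. With those genes kept, the CA1 median was -0.32 ± 0.257 (SE of the median), below the bound by less than its SE, against -0.52 ± 0.336 for dentate markers. That median cannot decide it either, since the called genes kept in it are the pattern to be explained. A difference in dissection was not tested. Striatum dissection markers had a median of 0.89 with 11 of 11 positive, while thalamus and neocortex markers did not pass the camera test.

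Genes of more than 1000 mean counts in tissue whose log2 ratio of control 1 to the other controls was below 0.35 included 24 in runs of neighbours, 18 on chromosome 10 (such as Sbno2 and Abca7) and 6 on the X chromosome (such as Reps2 and Rbbp7), with 2.67 to 8.19% of counts. Their median ratio of 0.976, against 2.14 over 2396 genes, was fixed by that choice, so it does not decide whether their counts follow depth. A single signal shared by all members of a run was excluded, with a median correlation of 0.0443 within runs against 0.186 between them. A signal per strand is consistent with the X run, at 0.998 on 1 strand and -0.70 between strands, and cannot be told apart for chromosome 10, at 0.759 and -0.41, too far below the bound of 0.95. The chromosome 10 value pools minus-strand genes whose counts moved differently, such as Polrmt (5962 and 6081 in N+F libraries 3 and 4) and Sbno2 (133388 and 87212). A signal per strand and shorter stretch was not tested there. No biological explanation was tested.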

How the results depend on the processing

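Chosen after seeing the data were the settings without the runs and Rn45s, the same 6 libraries without a block, the list settings with other size factors and filters, and the shares with no minimum in the N+F pair. Tissue genes higher with N+F (1) were 60 with DESeq2, 2 without a filter, 0 at 1 CPM or more, 0 without the runs and Rn45s and 0 to 1 leaving out a library. Genes lower (16) were 71 with DESeq2, 27 without a filter and 0 to 28 leaving out a library. With replicate numbers as a block edgeR gave 0 and 0 (1541 at an unadjusted p under 0.05), and the same 6 libraries without a block also 0 and 0 (1544); the numbers do not pair the libraries (r = -0.00, -0.08 and 0.13), and leaving out N+F library 4 alone gives the same 0. Pathway lists past the test (6) were 0 with an estimated correlation, 0 with fry, 10 without a filter and 4 to 10 leaving out a library; marker lists (8) were 0 with an estimated correlation and 0 with fry. Leaving out a library, Nr4a2 ran from -0.47 to 0.11, with its sign turned without control 3. Mapt ran from -0.075 to 0.14, with its sign turned without control 1 (-0.047), control 3 (-0.053) or N+F library 3 (-0.075).

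In the cultures, genes higher with amyloid beta were 3728 at 1.5-fold. Genes higher with N+F were 419 with a pseudocount of 0.1 and 699 at 1.5-fold, and genes lower 30 and 155. The additive fit of N+F gave 420 higher and 57 lower with DESeq2, and that of amyloid beta 794 to 3874 higher and 1156 to 4107 lower leaving out a library, where a group left with 1 sample is assumed to vary like the others. With no minimum in the N+F pair, the share of genes lower with amyloid beta in cortical glia that were higher with N+F in hippocampal glia went from 69.8% to 65.1%. Where not stated the cause was not tested. Low counts limit Foxa2 in tissue, which at 1 to 26 counts per library is below the count filter. Over all settings of single tissue genes and lists, 337 of 518 were the same, 177 weaker and 4 reversed; in cultures, of 74 values of 37 single gene ratios under another setting 52 were the same and 22 moved. Of the main results 33 of 60 values in tissue and 49 of 65 in cultures were the same.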

Other observations

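The subfield lists were chosen after the tissue results were seen. Outside the called genes, dentate gyrus markers had a median log2 fold change of -0.52 over 11 genes in the N+F hippocampus (limma camera p = 0.0166; p = 0.250 with an estimated correlation), and CA3 markers -0.22 over 8 genes (p = 0.104). The 3 called CA1 markers had a median of -1.51. Over all 14 CA1 markers it was -0.32.

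Blood cell markers differed between tissue libraries of 1 group, at 77.0, 87.1 and 339 CPM in controls and 197, 269, 193 and 175 CPM with N+F.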
